A study of Homo sapiens with 12 samples.

How the data were processed

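RNA sequencing of the human cervical squamous carcinoma line SiHa, which carries human papillomavirus 16, was used in 4 groups of 3 libraries at 48 h. The groups were untreated cells (Ctrl), cells given a single dose of 6 Gy (IR), cells given oleic acid (OA) and cells given both (OA+IR), as read from the sample titles and the series design. The oleic acid dose, and whether it was given before or after radiation, were not given in the sources used here. The labels did not say whether the 3 libraries of a group came from separate cultures, so every p-value measured only the spread between these samples, which may be technical. The library labels named ribosomal depletion (KAPA RiboErase) and poly-A selection together with an RNeasy Plus Micro kit, and which of the selections applied to these libraries was not settled here.

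Per the submitters' processing notes, reads were demultiplexed with bcl2fastq, aligned to GRCh38 with STAR 2.5.1a and assigned to genes with featureCounts 1.4.6-p5 from Subread. The annotation release and the strand setting were not given in the sources used here. The deposited values were CPM (reads of a gene scaled to 1 M assigned reads). Whole reads were recovered from them by dividing by the value of 1 read in each library, and all of the 661116 values checked lay within 0.001 of a whole number of reads (100%). Of 55209 entries, 116 repeated a gene and were left out, which gave 55093 genes. A further 7 columns belonged to no sample of the series and were not used here. Between 0.271% and 0.952% of the reads of a library were in no entry.

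Libraries held 15.7 to 28.8 M assigned reads, and the group means were 22.1, 18.7, 23.8 and 18.7 M for Ctrl, IR, OA and OA+IR. A gene was tested where its CPM was at least 1 in at least 3 libraries. This left 18039 genes, 13047 of them protein coding and 2412 long non-coding, and 18033 had a length and a GC content in the GENCODE 29 annotation. Chi-square values per degree of freedom between the reads of all 66 pairs of libraries ran from 3.50 to 77.5, above the value of 1 for repeated draws of a single library, so no library was present under more than 1 name.

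Expression was compared on log2(CPM + 0.5) with limma 3.58.1 (trended empirical Bayes, 1 mean per group, 8 residual degrees of freedom) in R 4.3.3. Fold changes were on this scale, which understates changes of genes with low values. The 5 comparisons were IR against Ctrl, OA against Ctrl, OA+IR against Ctrl, OA+IR against IR and OA+IR against OA. A sixth test, the interaction, asked whether the radiation effect differed with oleic acid. P-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison, and 0.05 was the threshold. Levels are given as mean ± SD of CPM, n = 3.

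Camera of limma tested 23 gene lists, with direction relative to all other genes. The inter-gene correlation was preset at 0.01, with adjustment over all 138 tests. A second setting estimated it from the data. The lists were p53 targets, PPAR targets, fatty acid oxidation, lipid droplets and triglyceride, fatty acid synthesis (SREBP1), cholesterol synthesis (SREBP2), G2/M and mitosis, G1/S and replication, DNA repair, apoptosis, integrated and endoplasmic reticulum stress, NRF2 and oxidative stress, interferon response, NF-kB and secretory inflammation, hypoxia and glycolysis, nuclear-encoded oxidative phosphorylation, squamous differentiation, mesenchymal genes and TGF-beta, replication-dependent histones, mitochondrial-encoded genes, ribosomal proteins, leukocyte markers, and fibroblast and endothelial markers.

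Genes were named by a rule set before the data were examined. It took 12 fixed genes (among them CDKN1A, MDM2, PPARG, PPARA, PPARD, PLIN2, PDK4, ANGPTL4, CPT1A, FABP4 and CD36), the 6 largest rises and the 6 largest falls of each comparison among genes that passed with a mean of at least 5 CPM in the higher group and libraries that did not overlap, and up to 4 members of each list with the smallest p. For the interaction the condition on overlap was not applied. Some genes that the rule named are not reported here. The comparisons, the lists, this rule and 24 alternative settings were set before the data were examined. They covered scaling (TMM and median of ratios), edgeR 4.0.16 and DESeq2 1.42.0 on whole reads, filters, pseudocounts, array weights, a replicate block, fits of only the groups compared, an estimated correlation and leaving out each library. A further 3 settings were added after the data were seen. Calculations also used Python 3.11.15 and matplotlib 3.10.9.

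The main within-group axis was the first singular vector of the log2 values after each group mean was subtracted, and it held 42.5% of that variance. Libraries with the same number were checked for pairing through the correlation of these deviations, with a threshold of 0.1 for every pair. The correlations were 0.135 to 0.364 for Ctrl and IR, 0.117 to 0.5 for Ctrl and OA and 0.129 to 0.442 for IR and OA, so the numbers paired there. Every pair of groups with OA+IR held at least 1 correlation under the threshold (as low as -0.183).

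The procedure was tested on simulated data of 18039 genes with 200 changed. For a pair of groups, limma recovered 44.8% of genes changed 1.5-fold, 70.1% at 2-fold and 92.4% at 4-fold, with 7 false calls. For the interaction it recovered 29.9%, 53.7% and 75.8%, with 11 false calls.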

Results

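The first question was how single genes named by the series design behaved across the 4 groups. PPARG (ENSG00000132170, chromosome 3, 12287368 to 12434356, plus strand), the nuclear receptor of adipocyte differentiation, stood at 19.7 ± 1.11 CPM, 19.3 ± 1.62 CPM, 22.8 ± 2.47 CPM and 23.9 ± 1.03 CPM in Ctrl, IR, OA and OA+IR and passed in no comparison. The related receptors PPARA and PPARD passed in 1 comparison each: PPARA fell in OA+IR against OA (30.5 ± 0.678 to 23.2 ± 1.58 CPM) and PPARD rose in OA+IR against IR (35.95 ± 0.663 to 44.8 ± 6.59 CPM). The PPARA call was lost without OA 1 (0.067), OA 2 (0.066), OA+IR 1 (0.064) or OA+IR 2 (0.068). The PPARD call was lost with median-of-ratios scaling (0.074) and without 7 of the 12 libraries, among them IR 3 (0.1) and OA+IR 3 (0.16). Of the fixed genes, PDK4 (0, 2, 2 and 9 reads over the 3 libraries of each group), the fatty acid transporter CD36 (29, 26, 41 and 28 reads) and FABP4 (0 reads in every library) were too low to be tested.

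The second question was what radiation changed in cells without oleic acid. In IR against Ctrl, 351 genes rose and 295 fell of 18039 tested, and 47 of the rises and 4 of the falls were at least 2-fold. CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339, plus strand), which encodes the cell cycle inhibitor p21, rose from 125 ± 7.02 to 217 ± 13.03 CPM (1.73-fold, adjusted p = 2e-05). MDM2 (ENSG00000135679, chromosome 12, 68808176 to 68850686, plus strand), a ubiquitin ligase, rose from 114 ± 1.86 to 148 ± 4.6 CPM (1.3-fold, adjusted p = 0.0013). Among genes with at least 5 CPM in the higher group and libraries that did not overlap, the largest rise was that of IL6 (ENSG00000136244, chromosome 7, 22725884 to 22732002, plus strand), an inflammatory cytokine, from 14.8 ± 1.41 to 47.8 ± 3.19 CPM (3.16-fold). Next within these limits were the mitochondrial carrier gene SLC25A45, the interferon-induced RNA-binding genes IFIT2 (2.96-fold) and IFIT3 (2.53-fold), and the stress-induced transcription factors ATF3 (2.86-fold) and JUN (2.56-fold). SLC25A45 rested mostly on IR 1 (46.27 CPM, SD of the group 20.6), and without Ctrl 1, Ctrl 2 or Ctrl 3 its adjusted p was 0.11, 0.062 and 0.11. Within the same limits, the largest falls were those of the antisense transcript DIO3OS (log2 -1.1, with the strand setting not given in the sources used here), the trafficking GTPase RAB17 (-0.89), the simple-epithelial keratin KRT19 (-0.88), the aldo-keto reductase AKR1B10 (-0.86), the fatty acid desaturase SCD (-0.78) and the p38 kinase activator MAP2K6 (-0.72). The RAB17 call was lost with edgeR (0.055) and without most single libraries, including IR 3 (0.14). The AKR1B10 call was lost without Ctrl 1 (0.096), Ctrl 2 (0.072), Ctrl 3 (0.077), IR 1 (0.058) or IR 2 (0.12).

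Among p53 targets in IR against Ctrl, 11 of 38 rose, 0 fell and 27 did not pass (16 and 1 adjusted over the list alone), and the list test gave adjusted p = 5.9e-07. Beside CDKN1A and MDM2, the growth factor GDF15 (2.72-fold) and the growth arrest gene GADD45A (1.71-fold) rose. Without Ctrl 2 or IR 1 the count of risen targets was 7, as with TMM or median of ratios, and without IR 2 it was 5. Mitotic genes moved together: 19 of 49 rose, 0 fell and 30 did not pass (33 and 0 adjusted over the list alone), with a median log2 change of 0.23 and adjusted p = 3.3e-23. The spindle kinesin KIF2C (1.3-fold), the microtubule-binding genes HMMR (1.4-fold) and NUSAP1 (1.29-fold) and the checkpoint kinase BUB1 (1.31-fold) rose. The count was 9 with TMM, 8 with median of ratios, 11 without Ctrl 1, Ctrl 3, IR 1 or IR 2, and 12 without Ctrl 2. For G1/S and replication, 3 of 46 rose, 0 fell and 43 did not pass (3 and 0 adjusted over the list alone), among them the origin recognition gene ORC6 (1.32-fold) and the thymidylate synthase TYMS (1.29-fold), with adjusted p = 0.021 and adjusted p = 0.29 with an estimated correlation. That call was lost without Ctrl 1 (0.062) and IR 3 (0.15), with median-of-ratios scaling (0.077) and with TMM (0.079).

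Inflammatory genes rose with radiation. In the NF-kB and secretory list, 18 of 32 rose, 0 fell and 14 did not pass (22 and 0 adjusted over the list alone), with a median log2 change of 0.54 and adjusted p = 2.9e-22. The growth factor EREG (1.57-fold), the prostaglandin synthase PTGS2 (1.86-fold) and the NF-kB feedback gene TNFAIP3 (1.65-fold) rose beside IL6. In the interferon list, 13 of 40 rose, 0 fell and 27 did not pass (25 and 0 adjusted over the list alone), with a median of 0.41 and adjusted p = 5e-13, which became adjusted p = 0.18 with an estimated correlation. The antiviral genes OASL (2.28-fold) and SAMD9 (1.45-fold) rose with IFIT2 and IFIT3. Without Ctrl 1 or Ctrl 3 the count was 7, without Ctrl 2 it was 8 and without IR 1 it was 5. For mesenchymal genes and TGF-beta, 9 of 28 rose, 0 fell and 19 did not pass (13 and 0 adjusted over the list alone), among them the matrix gene THBS1 (1.37-fold) and the ligand TGFB2 (1.33-fold), with adjusted p = 2.5e-06. That count was 5 with TMM, 4 with median of ratios, 3 without Ctrl 1 and 4 without Ctrl 2, IR 1 or IR 3.

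Lipid synthesis genes fell with radiation. In the cholesterol list, 0 of 26 rose, 11 fell and 15 did not pass (0 and 15 adjusted over the list alone), with a median of -0.28 and adjusted p = 2.6e-14. The mevalonate enzyme MVD (log2 -0.49), the sterol sensor partner INSIG1 (-0.55), the last-step reductase DHCR7 (-0.55) and the transcription factor SREBF2 (-0.35) fell. In fatty acid synthesis, 0 of 23 rose, 8 fell and 15 did not pass (1 and 10 adjusted over the list alone), with a median of -0.18 and adjusted p = 1.5e-08. SCD (ENSG00000099194, chromosome 10, 100347124 to 100364834, plus strand) fell from 1007 ± 19.5 to 585 ± 33.4 CPM, and the lipogenic transcription factor SREBF1 (log2 -0.46) and the desaturase FADS2 (-0.4) fell. Without Ctrl 2 or IR 1 the cholesterol count was 7, and without Ctrl 1, Ctrl 2, IR 1 or IR 2 the fatty acid synthesis count was 5. For fatty acid oxidation, 0 of 29 rose, 1 fell and 28 did not pass (0 and 2 adjusted over the list alone), with adjusted p = 0.0028 downward and adjusted p = 0.12 with an estimated correlation. PPAR targets had no common direction: 2 of 19 rose, 0 fell and 17 did not pass (3 and 0 adjusted over the list alone, list test adjusted p = 0.98), and the rise of ANGPTL4 (ENSG00000167772, chromosome 19, 8363289 to 8374373, plus strand), a lipase inhibitor, from 1.94 ± 0.0246 to 3.31 ± 0.508 CPM was lost in a fit of only these groups (0.11). For lipid droplets and triglyceride, 1 of 25 rose, 0 fell and 24 did not pass (1 and 1 adjusted over the list alone, list test adjusted p = 0.7), the rise being that of the lipase inhibitor G0S2 (1.75-fold).

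For DNA repair in IR against Ctrl, 1 of 39 rose, 0 fell and 38 did not pass (1 and 0 adjusted over the list alone), with adjusted p = 0.027 upward and adjusted p = 0.42 with an estimated correlation. The call was lost without Ctrl 3 (0.095) and without IR 1 (0.1). For apoptosis, 3 of 33 rose, 0 fell and 30 did not pass (3 and 0 adjusted over the list alone, list test adjusted p = 0.091, 0.037 without IR 2 and 0.04 with a filter of 5 CPM), among them the caspase inhibitor BIRC3 (1.75-fold). For integrated stress, 4 of 34 rose, 3 fell and 27 did not pass (9 and 6 adjusted over the list alone, list test adjusted p = 0.93), where the phosphatase subunit PPP1R15A rose (1.3-fold) and the serine synthesis gene PSAT1 fell (log2 -0.45). Single libraries moved these calls: 1 member fell without Ctrl 1, Ctrl 3, IR 1 or IR 2, and 2 rose without IR 2 or IR 3. For NRF2, 2 of 31 rose, 4 fell and 25 did not pass (4 and 11 adjusted over the list alone), with adjusted p = 9.3e-05 downward and adjusted p = 0.23 with an estimated correlation. Superoxide dismutase SOD2 rose (1.5-fold), AKR1C3 fell (log2 -0.58), and the fallen count was 2 without Ctrl 1 and 1 without Ctrl 3, IR 1 or IR 2. For hypoxia, 1 of 32 rose, 2 fell and 29 did not pass (3 and 4 adjusted over the list alone), with adjusted p = 0.027 downward and adjusted p = 0.38 with an estimated correlation. The call was lost without Ctrl 3 (0.12) and IR 2 (0.17), with median-of-ratios scaling (0.058), TMM (0.054) and a filter of 5 CPM (0.14). For squamous differentiation, 0 of 21 rose, 1 fell and 20 did not pass (0 and 1 adjusted over the list alone), with adjusted p = 0.009 downward and adjusted p = 0.08 with an estimated correlation. A filter of 5 CPM ended that call (0.092).

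The split of the 646 genes was 54.3% up. Median-of-ratios scaling gave 417, TMM 435, edgeR 417 and DESeq2 753. The replicate block gave 1618 (870 up and 748 down), and leaving out Ctrl 1, Ctrl 2, Ctrl 3, IR 1 or IR 2 gave 297, 295, 303, 261 and 266. With the block 23 interferon genes and 4 DNA repair genes rose, 8 NRF2 genes, 2 squamous genes and 2 fatty acid oxidation genes fell, and hypoxia (2 risen and 8 fallen), integrated stress (8 and 5) and lipid droplets (2 and 2) also held more changes.

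**Figure D1:**
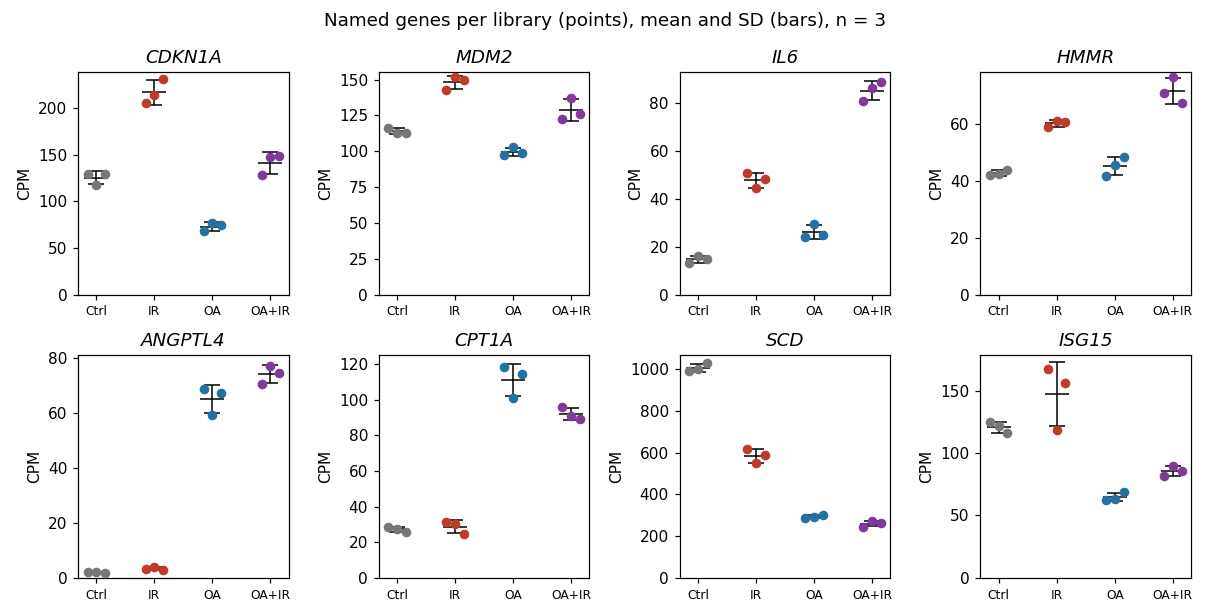
Levels of 8 genes in each of the 12 libraries, with mean and SD per group.

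The third question was what oleic acid changed in cells that were not irradiated. In OA against Ctrl, 811 genes rose and 590 fell, and 71 and 85 of them were at least 2-fold. ANGPTL4 rose from 1.94 ± 0.0246 to 64.9 ± 4.999 CPM (26.7-fold). CPT1A (ENSG00000110090, chromosome 11, 68754620 to 68844410, minus strand), the entry enzyme of mitochondrial fatty acid oxidation, rose from 27.2 ± 1.49 to 111 ± 9.11 CPM, and PLIN2 (ENSG00000147872, chromosome 9, 19108375 to 19149290, minus strand), a coat protein of lipid droplets, rose from 40.7 ± 1.23 to 86.5 ± 10.5 CPM. Under the limits given above, the other large rises were those of stress-responsive genes: the hormone STC2 (8.58-fold), NIBAN1 (7.01-fold), the peptide gene ADM2 (6.34-fold), GDF15 (6.03-fold) and the pseudokinase TRIB3 (4.15-fold). Under the same limits the largest falls were those of the endocytic receptor LRP2 (ENSG00000081479, chromosome 2, 169127109 to 169362685, minus strand; log2 -2.99), the keratins KRT15 (-2.81), KRT4 (-2.77) and KRT19 (-2.23), the sterol exporter ABCG1 (-2.13) and SCD (-1.78). CDKN1A fell from 125 ± 7.02 to 72.95 ± 4.58 CPM (adjusted p = 3.5e-06), while the fall of MDM2 (log2 -0.19) was lost without most single libraries, for example OA 1 (0.15) and OA 3 (0.069).

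Lipid lists answered in opposite directions. Among PPAR targets, 5 of 19 rose, 2 fell and 12 did not pass (5 and 2 adjusted over the list alone), with a median of 0.17, adjusted p = 0.00056 and adjusted p = 0.052 with an estimated correlation. The acyl-CoA dehydrogenase ACADVL (2.27-fold) rose with ANGPTL4, CPT1A (4.03-fold) and PLIN2 (2.1-fold). For lipid droplets, 6 of 25 rose, 1 fell and 18 did not pass (6 and 1 adjusted over the list alone), with adjusted p = 0.021 upward and adjusted p = 0.1 with an estimated correlation. G0S2 (2.37-fold), the droplet coat gene PLIN4 (2.92-fold) and the acyltransferase GPAM (1.4-fold) rose, and the list's call was lost with median-of-ratios scaling (0.06), with TMM (0.061) with array weights (0.061) and without OA 3 (0.1). For fatty acid oxidation, 5 of 29 rose, 0 fell and 24 did not pass (6 and 1 adjusted over the list alone, list test adjusted p = 0.12). The risen count was 2 with either scaling and 3 without Ctrl 1, Ctrl 2, Ctrl 3 or OA 2, and the list passed without Ctrl 3 (0.024), OA 2 (0.031) or a filter (0.029). In the cholesterol list, 1 of 26 rose, 16 fell and 9 did not pass (1 and 19 adjusted over the list alone), with a median of -0.34 and adjusted p = 2.9e-19, and 10 fell without Ctrl 3 or OA 1. INSIG1 (log2 -1.3), the cyclase LSS (-0.8), DHCR7 (-0.93) and MVD (-0.57) fell. In fatty acid synthesis, 3 of 23 rose, 9 fell and 11 did not pass (3 and 10 adjusted over the list alone), with adjusted p = 1.4e-09. SCD fell from 1007 ± 19.5 to 294 ± 5.32 CPM, and SREBF1 (log2 -1.41) and FADS2 (-1.18) fell.

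In integrated stress in OA against Ctrl, 16 of 34 rose, 1 fell and 17 did not pass (17 and 3 adjusted over the list alone), with adjusted p = 1.4e-09 and adjusted p = 0.089 with an estimated correlation. TRIB3, the cystine transporter SLC7A11 (2.74-fold), the asparagine synthetase ASNS (3.78-fold) and the transcription factor ATF4 (1.84-fold) rose. In the interferon list, 0 of 40 rose, 20 fell and 20 did not pass (0 and 28 adjusted over the list alone), with a median of -0.48, adjusted p = 2e-25 and adjusted p = 0.061 with an estimated correlation. The ubiquitin-like gene ISG15 (log2 -0.9) and the interferon-induced genes IFI27 (-1.02), IFI6 (-0.79) and MX1 (-1.03) fell. In squamous differentiation, 1 of 21 rose, 10 fell and 10 did not pass (2 and 12 adjusted over the list alone), with a median of -0.43 and adjusted p = 1.2e-10, and 6 fell without OA 1. The keratins KRT4, KRT15 and KRT17 (log2 -0.74) fell and the iron-binding gene LCN2 rose (2.15-fold). Keratins may share reads. Among p53 targets, 2 of 38 rose, 7 fell and 29 did not pass (2 and 11 adjusted over the list alone), with adjusted p = 2.1e-05 downward, where the ligand KITLG fell (log2 -1.1) and the stress gene SESN2 rose (1.76-fold) with GDF15.

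The NRF2 list was mixed: 5 of 31 rose, 7 fell and 19 did not pass (5 and 9 adjusted over the list alone), with adjusted p = 0.02 downward and adjusted p = 0.43 with an estimated correlation. The exporter ABCC3 (2.04-fold) and the catalase gene CAT (1.45-fold) rose and AKR1B10 fell (log2 -1.57). The call was lost without Ctrl 3 (0.2, 4 members down) and OA 1 (0.12). For NF-kB, 6 of 32 rose, 5 fell and 21 did not pass (9 and 7 adjusted over the list alone, list test adjusted p = 0.56), where EREG (1.86-fold), PTGS2 (1.79-fold) and IL6 (1.74-fold) rose and TNFAIP2 fell (log2 -0.63), and 3 fell without Ctrl 1, OA 1 or OA 2. For mesenchymal genes, 6 of 28 rose, 5 fell and 17 did not pass (6 and 6 adjusted over the list alone, list test adjusted p = 0.65). For hypoxia, 3 of 32 rose, 4 fell and 25 did not pass (4 and 9 adjusted over the list alone), with adjusted p = 0.0065 downward and adjusted p = 0.29 with an estimated correlation. Here the hexokinase HK2 rose (1.52-fold) and NDRG1 fell (log2 -0.46), and 7 fell without OA 3 or OA+IR 1. For DNA repair, 6 of 39 rose, 0 fell and 33 did not pass (8 and 0 adjusted over the list alone), with adjusted p = 0.00032 upward and adjusted p = 0.23 with an estimated correlation. BRCA1, a recombination gene, rose (1.38-fold), and the count was 2 with TMM, 3 with median of ratios, 1 without Ctrl 3 or OA 2, 2 without OA 1 and 10 without OA 3.

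The cell cycle lists did not pass with oleic acid alone. For mitosis, 1 of 49 rose, 0 fell and 48 did not pass (1 and 0 adjusted over the list alone, list test adjusted p = 0.057), and the list passed with the replicate block (0.036, 10 risen), without a filter (0.0021), without Ctrl 3 (0.027) and without OA 1 (0.0042), with 4 risen without IR 3 or OA 3 and 3 without OA+IR 1. For G1/S, 2 of 46 rose, 0 fell and 44 did not pass (1 and 0 adjusted over the list alone, list test adjusted p = 0.5), with 4 risen without OA 3, and the chromatin gene CDCA7 rose (1.41-fold). For apoptosis, 0 of 33 rose, 1 fell and 32 did not pass (0 and 1 adjusted over the list alone, list test adjusted p = 0.13), with 3 fallen without OA 3. Of the 1401 genes, 57.9% rose, against 38.5% of 1135 (437 up and 698 down) with median-of-ratios scaling and 437 up and 745 down with TMM, so the excess of rises rested on the scaling. The replicate block gave 2687 (1767 up and 920 down), and 892, 870 and 866 passed without Ctrl 3, OA 1 and OA 2. With the block 15 DNA repair genes, 5 G1/S genes and 2 squamous genes rose, 11 p53 targets, 3 apoptosis genes, 2 lipid droplet genes and 2 integrated stress genes fell, and 5 hypoxia genes rose while 9 fell.

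The fourth question was how cells with both treatments differed from untreated cells. In OA+IR against Ctrl, 2499 genes rose and 2030 fell, and 324 and 123 were at least 2-fold. ANGPTL4 rose from 1.94 ± 0.0246 to 73.9 ± 3.19 CPM (30.5-fold), and the protease inhibitors SERPINB3 (18.8-fold) and SERPINB4 (16.1-fold) followed. These neighbours are close in sequence, so reads may be shared between them. The kinase feedback gene SPRY4 (10.2-fold), the protease inhibitor SERPINB2 (9.79-fold) and the mitochondrial 12S rRNA gene MT-RNR1 (9.31-fold) came next within the limits given above. MT-RNR1 was lost without Ctrl 1 (0.086), Ctrl 3 (0.13), OA+IR 1 (0.15) or OA+IR 3 (0.1). Of the genes within these limits, those that fell most were LRP2 (log2 -4.18), KRT4 (-3.03), KRT19 (-3.01), KRT15 (-2.27), the matrix gene NPNT (-2.23) and the salt transporter SLC12A3 (-2.2). CDKN1A was 142 ± 11.7 CPM and did not pass (adjusted p = 0.091). CPT1A (3.34-fold) and PLIN2 (2.51-fold) rose.

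For mitosis in OA+IR against Ctrl, 37 of 49 rose, 0 fell and 12 did not pass (40 and 0 adjusted over the list alone), with a median of 0.31 and adjusted p = 1.5e-14, among them HMMR (1.67-fold), BUB1 (1.47-fold), the kinesin KIF14 (1.92-fold) and the topoisomerase TOP2A (1.37-fold). For NF-kB, 21 of 32 rose, 3 fell and 8 did not pass (22 and 3 adjusted over the list alone), with a median of 0.8 and adjusted p = 2.7e-09, among them EREG (3.31-fold), IL6 (5.62-fold), PTGS2 (4.14-fold) and the cytokine LIF (3.28-fold). For cholesterol synthesis, 3 of 26 rose, 18 fell and 5 did not pass (3 and 19 adjusted over the list alone), with adjusted p = 3.5e-11, and no member rose without Ctrl 1, Ctrl 3 or OA+IR 3 and 1 without OA+IR 1. For fatty acid synthesis, 3 of 23 rose, 11 fell and 9 did not pass (3 and 12 adjusted over the list alone), with adjusted p = 4e-07 and adjusted p = 0.057 with an estimated correlation. SCD fell from 1007 ± 19.5 to 259 ± 13.4 CPM. For squamous differentiation, 1 of 21 rose, 13 fell and 7 did not pass (1 and 14 adjusted over the list alone), with a median of -0.62 and adjusted p = 2.7e-08, among them the junction genes PKP3 (log2 -0.62) and PPL (-0.87). For interferon, 4 of 40 rose, 13 fell and 23 did not pass (5 and 15 adjusted over the list alone), with adjusted p = 0.012 downward and adjusted p = 0.57 with an estimated correlation. Among the falls were BST2 (log2 -0.51) and CMPK2 (-0.77), and 8 fell without Ctrl 1 and 7 without Ctrl 2.

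For p53 targets in OA+IR against Ctrl, 8 of 38 rose, 9 fell and 21 did not pass (9 and 11 adjusted over the list alone, list test adjusted p = 0.36), where the stress kinase PLK3 rose (1.7-fold) and the membrane gene NINJ1 fell (log2 -0.72). For PPAR targets, 6 of 19 rose, 1 fell and 12 did not pass (7 and 2 adjusted over the list alone), with adjusted p = 0.028 upward and adjusted p = 0.18 with an estimated correlation. The call was lost without OA+IR 2 (0.058) and OA+IR 3 (0.069). For integrated stress, 18 of 34 rose, 8 fell and 8 did not pass (21 and 8 adjusted over the list alone), with adjusted p = 0.00014 upward and adjusted p = 0.23 with an estimated correlation. Of the members, 5 fell without Ctrl 1 or Ctrl 3 and 4 without OA+IR 1. For NRF2, 4 of 31 rose, 19 fell and 8 did not pass (6 and 21 adjusted over the list alone), with adjusted p = 3.5e-07 downward and adjusted p = 0.17 with an estimated correlation. Among the falls was the haem oxygenase HMOX1 (log2 -1.14). For DNA repair, 22 of 39 rose, 1 fell and 16 did not pass (24 and 1 adjusted over the list alone), with adjusted p = 2.4e-05 upward and adjusted p = 0.19 with an estimated correlation. Of the members, 13 rose without Ctrl 3 and 14 without OA+IR 1. For G1/S, 12 of 46 rose, 2 fell and 32 did not pass (12 and 2 adjusted over the list alone), with adjusted p = 0.015 upward and adjusted p = 0.26 with an estimated correlation. The call was lost without OA+IR 3 (0.062), with median-of-ratios scaling (0.13, 7 risen) and with TMM (0.12, 8 risen). For mesenchymal genes, 12 of 28 rose, 5 fell and 11 did not pass (12 and 5 adjusted over the list alone), with adjusted p = 0.012 upward and adjusted p = 0.22 with an estimated correlation. TGFB2 (2.03-fold) and THBS1 (1.89-fold) rose, and 3 members fell without Ctrl 3 or OA+IR 1.

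For fatty acid oxidation in OA+IR against Ctrl, 3 of 29 rose, 9 fell and 17 did not pass (3 and 11 adjusted over the list alone, list test adjusted p = 0.089, 0.048 without OA+IR 2 and 0.019 without a filter), with 5 fallen without Ctrl 2, 2 without Ctrl 3 and 3 without OA+IR 1. For lipid droplets, 7 of 25 rose, 5 fell and 13 did not pass (7 and 5 adjusted over the list alone, list test adjusted p = 0.65), where LPIN2 rose (1.24-fold) and the fallen count moved with single libraries to between 0 and 3. For apoptosis, 7 of 33 rose, 7 fell and 19 did not pass (10 and 7 adjusted over the list alone, list test adjusted p = 0.81), where the survival gene MCL1 rose (1.33-fold), CASP9 fell (log2 -0.42), 4 rose with either scaling and 2 fell without OA+IR 1. For hypoxia, 5 of 32 rose, 12 fell and 15 did not pass (5 and 16 adjusted over the list alone), with adjusted p = 0.0072 downward and adjusted p = 0.29 with an estimated correlation. With median-of-ratios scaling 1931 genes rose and 2481 fell (43.8% up), against 55.2% up in the values above, and TMM gave 1976 and 2462.

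The fifth question was what oleic acid changed in irradiated cells. In OA+IR against IR, 1062 genes rose and 974 fell, and 75 and 97 were at least 2-fold. ANGPTL4 rose from 3.31 ± 0.508 to 73.9 ± 3.19 CPM, CPT1A from 28.7 ± 3.74 to 92.1 ± 3.46 CPM and PLIN2 from 42.5 ± 0.661 to 103 ± 12.4 CPM. SERPINB3 (7.23-fold), SERPINB4 (6.51-fold), STC2 (4.87-fold), ADM2 (4.55-fold) and SPRY4 (4.3-fold) rose. LRP2 (log2 -3.57), KRT4 (-2.6), KRT19 (-2.13), the natriuretic peptide receptor NPR3 (-1.88), SLC12A3 (-1.84) and the death ligand TNFSF10 (-1.79) fell most within the limits given above. CDKN1A fell from 217 ± 13.03 to 142 ± 11.7 CPM (adjusted p = 3.6e-05). Among p53 targets, 2 of 38 rose, 13 fell and 23 did not pass (2 and 18 adjusted over the list alone), with a median of -0.2 and adjusted p = 1.4e-07. NINJ1 (log2 -0.67), the kinase PLK2 (-0.43) and the antiproliferative gene BTG2 (-0.74) fell, and the count was 8 without IR 1, OA+IR 1 or OA+IR 3.

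Interferon genes fell in this comparison: 0 of 40 rose, 22 fell and 18 did not pass (0 and 31 adjusted over the list alone), with a median of -0.51, adjusted p = 3.4e-21 and adjusted p = 0.088 with an estimated correlation, and 14 fell without IR 1. CMPK2 (log2 -0.89), ISG15 (-0.76) and the signalling gene STAT2 (-0.52) were among them. In squamous differentiation, 0 of 21 rose, 11 fell and 10 did not pass (0 and 11 adjusted over the list alone), with adjusted p = 1.5e-08, including KRT17 (log2 -0.72). For PPAR targets, 5 of 19 rose, 1 fell and 13 did not pass (6 and 2 adjusted over the list alone), with adjusted p = 0.0012 upward and adjusted p = 0.061 with an estimated correlation. For integrated stress, 15 of 34 rose, 3 fell and 16 did not pass (17 and 4 adjusted over the list alone), with adjusted p = 2.1e-05 upward and adjusted p = 0.21 with an estimated correlation. Risen members included ASNS (3.93-fold) and PSAT1 (2.38-fold). For cholesterol synthesis, 3 of 26 rose, 9 fell and 14 did not pass (3 and 12 adjusted over the list alone), with adjusted p = 4e-06 downward and adjusted p = 0.061 with an estimated correlation. Here INSIG1 fell (log2 -0.84). For fatty acid synthesis, 3 of 23 rose, 6 fell and 14 did not pass (5 and 9 adjusted over the list alone), with adjusted p = 0.0013 downward and adjusted p = 0.19 with an estimated correlation. SCD fell from 585 ± 33.4 to 259 ± 13.4 CPM.

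For NRF2 in OA+IR against IR, 3 of 31 rose, 9 fell and 19 did not pass (3 and 16 adjusted over the list alone), with adjusted p = 2.5e-05 downward and adjusted p = 0.22 with an estimated correlation. Fallen members included HMOX1 (log2 -1.03). For DNA repair, 8 of 39 rose, 0 fell and 31 did not pass (13 and 0 adjusted over the list alone), with adjusted p = 9.7e-05 upward and adjusted p = 0.22 with an estimated correlation. Of the members, 5 rose without IR 2 or OA+IR 1 and 3 without IR 3. For mitosis, 6 of 49 rose, 1 fell and 42 did not pass (9 and 1 adjusted over the list alone), with adjusted p = 0.0089 upward and adjusted p = 0.16 with an estimated correlation. Here KIF18A rose (1.24-fold). That call was lost with median-of-ratios scaling (0.067), with TMM (0.058) and without OA+IR 2 (0.058), each with 3 risen, and 2 rose without IR 2 or OA+IR 1 and 1 without IR 3. For NF-kB, 11 of 32 rose, 5 fell and 16 did not pass (12 and 5 adjusted over the list alone, list test adjusted p = 0.054), and the list passed without Ctrl 1 (0.048), Ctrl 3 (0.045), IR 3 (0.034), OA 1 (0.042), OA 2 (0.045) or OA+IR 1 (0.047). It also passed with median-of-ratios scaling (0.021), TMM (0.023), a pseudocount of 1 (0.044) and no filter (0.033). EREG (2.11-fold) and PTGS2 (2.23-fold) rose. For mesenchymal genes, 9 of 28 rose, 5 fell and 14 did not pass (10 and 7 adjusted over the list alone, list test adjusted p = 0.35), with 5 risen without IR 3 or OA+IR 1 and TGFB1 among the rises (1.57-fold).

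For fatty acid oxidation in OA+IR against IR, 3 of 29 rose, 3 fell and 23 did not pass (3 and 3 adjusted over the list alone, list test adjusted p = 0.98), with 1 fallen without IR 3 and 0 without OA+IR 1. For lipid droplets, 5 of 25 rose, 2 fell and 18 did not pass (8 and 2 adjusted over the list alone, list test adjusted p = 0.12, 0.037 without OA+IR 1 and 0.038 without a filter), with 3 risen without IR 3. For G1/S, 4 of 46 rose, 1 fell and 41 did not pass (4 and 1 adjusted over the list alone, list test adjusted p = 0.25, 0.031 without OA+IR 1 and 0.044 with array weights), with 2 risen without IR 1, IR 2 or OA+IR 3. For hypoxia, 5 of 32 rose, 5 fell and 22 did not pass (5 and 8 adjusted over the list alone, list test adjusted p = 0.12, 0.042 without IR 2 and 0.026 without a filter), with 3 risen and 2 fallen without IR 3 and 3 fallen with either scaling. For apoptosis, 2 of 33 rose, 4 fell and 27 did not pass (3 and 6 adjusted over the list alone, list test adjusted p = 0.34), where BMF, a death-promoting gene, fell (log2 -1.49). The split was 52.2% up, against 41.4% with median-of-ratios scaling (713 up and 1010 down) and 745 up and 1002 down with TMM.

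The sixth question was what radiation changed in cells given oleic acid. In OA+IR against OA, 498 genes rose and 651 fell, and 53 and 5 were at least 2-fold. CDKN1A rose from 72.95 ± 4.58 to 142 ± 11.7 CPM (adjusted p = 1.6e-06) and MDM2 from 99.8 ± 2.77 to 129 ± 7.68 CPM (adjusted p = 0.00096). SERPINB3 (7.69-fold), SERPINB4 (6.11-fold), SERPINB2 (5.37-fold), IL6 (3.23-fold) and the activin subunit INHBA (2.99-fold) were among the largest rises within the limits given above. LRP2 (log2 -1.19), SLC12A3 (-1.12), the antisense transcript LINC00987 (-1.02), the aldo-keto reductases AKR1C2 (-1.02) and AKR1C3 (-0.89), which may share reads, and MAP2K6 (-0.93) fell most within the same limits. The LINC00987 call was lost without OA 1 (0.13), OA 2 (0.15) or OA+IR 1 (0.12), among others. ANGPTL4, PLIN2 and CPT1A did not pass (adjusted p = 0.38, 0.11 and 0.091).

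For mitosis in OA+IR against OA, 19 of 49 rose, 0 fell and 30 did not pass (32 and 0 adjusted over the list alone), with a median of 0.23 and adjusted p = 6.8e-24, including HMMR (1.58-fold), NUSAP1 (1.31-fold) and KIF18A (1.41-fold). For NF-kB, 22 of 32 rose, 0 fell and 10 did not pass (24 and 0 adjusted over the list alone), with a median of 0.58 and adjusted p = 1.5e-25, including EREG (1.78-fold), PTGS2 (2.31-fold) and TNFAIP3 (1.73-fold). For p53 targets, 9 of 38 rose, 1 fell and 28 did not pass (12 and 2 adjusted over the list alone), with adjusted p = 0.0028, including PLK3 (1.49-fold), while the RNA-binding gene ZMAT3 fell (log2 -0.32). For interferon, 14 of 40 rose, 0 fell and 26 did not pass (23 and 0 adjusted over the list alone), with a median of 0.35, adjusted p = 1.6e-12 and adjusted p = 0.19 with an estimated correlation. The risen count was 9 without OA 2, OA 3, OA+IR 1, OA+IR 2 or OA+IR 3. IFIT2 (2.74-fold), MX2 (2.42-fold) and OAS2 (1.67-fold) were among them. For mesenchymal genes, 8 of 28 rose, 0 fell and 20 did not pass (14 and 0 adjusted over the list alone), with adjusted p = 3.2e-09, including TGFB2 (1.41-fold) and the matrix signal CCN1 (1.35-fold).

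For fatty acid oxidation in OA+IR against OA, 0 of 29 rose, 7 fell and 22 did not pass (0 and 13 adjusted over the list alone), with a median of -0.17 and adjusted p = 6e-07, including the thiolase HADHB (log2 -0.34) and the isomerase ECI1 (-0.37). The fallen count was 2 with either scaling, 3 without OA 1, OA 3 or OA+IR 1 and 4 without OA+IR 3. For NRF2, 1 of 31 rose, 12 fell and 18 did not pass (1 and 20 adjusted over the list alone), with adjusted p = 2.7e-10 and adjusted p = 0.088 with an estimated correlation. Fallen members included HMOX1 (log2 -0.61), while SOD2 rose (1.61-fold). For integrated stress, 2 of 34 rose, 9 fell and 23 did not pass (2 and 12 adjusted over the list alone), with adjusted p = 0.013 downward and adjusted p = 0.4 with an estimated correlation. Fallen members included TRIB3 (log2 -0.71). It was lost without OA 3 (0.2) and OA+IR 1 (0.16), with a filter of 5 CPM (0.077) and with array weights (0.1). The fallen count was 2 with either scaling, 4 without OA 2, OA 3 or OA+IR 1 and 5 without OA+IR 3. For cholesterol synthesis, 2 of 26 rose, 4 fell and 20 did not pass (3 and 6 adjusted over the list alone), with adjusted p = 0.012 downward and adjusted p = 0.23 with an estimated correlation. Here SREBF2 (log2 -0.29) and MVD (-0.3) fell. It was lost without OA 3 (0.17) and OA+IR 1 (0.14), with a filter of 5 CPM (0.065) and with array weights (0.13), and 2 fell without OA+IR 1 or OA 1. For fatty acid synthesis, 2 of 23 rose, 2 fell and 19 did not pass (2 and 6 adjusted over the list alone, list test adjusted p = 0.089, 0.039 without OA 1 and 0.012 without a filter), where the ligase ACSL4 rose (1.44-fold).

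For G1/S in OA+IR against OA, 3 of 46 rose, 0 fell and 43 did not pass (3 and 0 adjusted over the list alone), with adjusted p = 0.003 upward and adjusted p = 0.21 with an estimated correlation. Risen members included ORC6 (1.32-fold) and UHRF1 (1.24-fold). For DNA repair, 1 of 39 rose, 0 fell and 38 did not pass (0 and 0 adjusted over the list alone), with adjusted p = 0.0046 upward and adjusted p = 0.33 with an estimated correlation. For apoptosis, 4 of 33 rose, 1 fell and 28 did not pass (4 and 1 adjusted over the list alone, list test adjusted p = 0.077), with BIRC3 (2.35-fold) and MCL1 (1.24-fold) among the rises, and the list passed without OA 3 (0.026) and OA+IR 1 (0.018), with a filter of 5 CPM (0.013) and with array weights (0.013). For PPAR targets, 1 of 19 rose, 3 fell and 15 did not pass (2 and 4 adjusted over the list alone, list test adjusted p = 0.42), with 1 fallen without OA+IR 1 or OA+IR 3. For lipid droplets, 1 of 25 rose, 2 fell and 22 did not pass (1 and 3 adjusted over the list alone, list test adjusted p = 0.26). For hypoxia, 3 of 32 rose, 2 fell and 27 did not pass (4 and 4 adjusted over the list alone, list test adjusted p = 0.39, and 0.049 without a filter), including the peptide gene ADM (1.55-fold). For squamous differentiation, 0 of 21 rose, 3 fell and 18 did not pass (0 and 5 adjusted over the list alone, list test adjusted p = 0.11, and 0.023 without OA 1). Of the 1149 genes 43.3% rose, against 55.1% of 753 with median-of-ratios scaling (415 up and 338 down) and 451 up and 324 down with TMM, and a fit of only these groups gave 490. Without OA 2, OA 3 and OA+IR 1, 734, 663 and 699 passed.

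**Figure D2:**
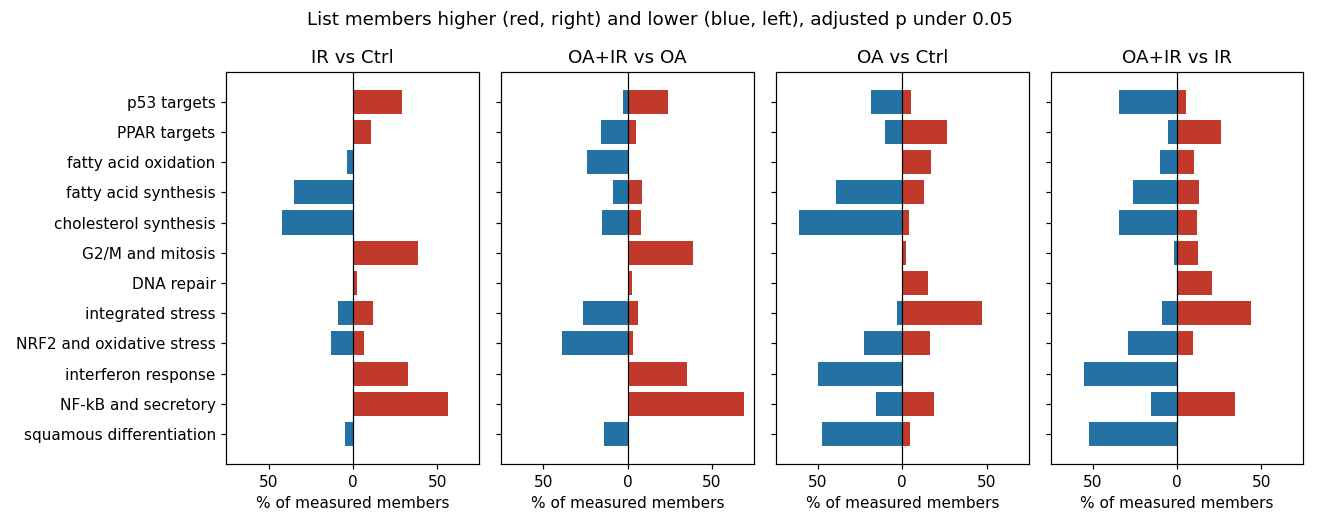
Percentage of measured members of 12 lists that rose or fell in 4 comparisons.

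The effects of each treatment with and without the other were compared over disjoint libraries. For oleic acid (OA against Ctrl, and OA+IR against IR), the log2 changes of the 18039 genes correlated with r = 0.663 (rank correlation 0.592). Of the 1401 genes that passed in OA against Ctrl, 1386 had the same sign in OA+IR against IR (98.9%), and 532 rose in both, 479 fell in both and 1 moved in opposite directions, where independence gave 47.7 and 31.9. ANGPTL4, CPT1A and PLIN2 rose in both, and LRP2, KRT4, KRT19 and SCD fell in both. For radiation (IR against Ctrl, and OA+IR against OA), r was 0.529 (rank correlation 0.512). Of 646 genes, 637 had the same sign (98.6%), with 227 risen in both and 169 fallen in both, against 9.69 and 10.6. CDKN1A, MDM2, IL6, IFIT2 and HMMR rose in both, and LRP2 fell in both.

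**Figure D3:**
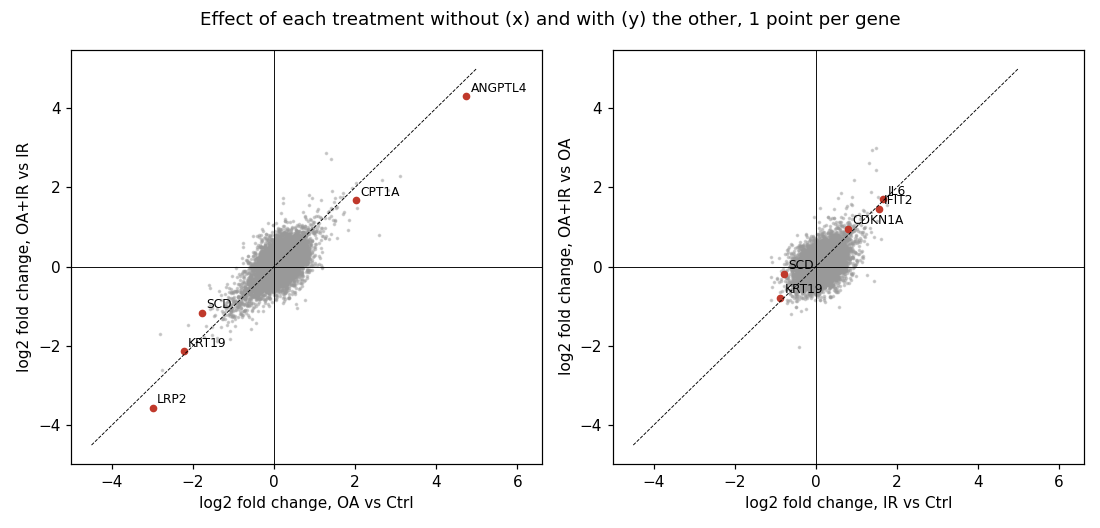
Log2 change of each gene for oleic acid and for radiation, without (horizontal) and with (vertical) the other treatment.

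The seventh question was whether the radiation effect differed with oleic acid. In the limma test of the interaction 2 genes passed, both with a radiation change that was higher (or a smaller fall) with oleic acid, called upward here, and 727 had an unadjusted p under 0.05. Of the genes that passed, SCD stood at 1007 ± 19.5 CPM, 585 ± 33.4 CPM, 294 ± 5.32 CPM and 259 ± 13.4 CPM in Ctrl, IR, OA and OA+IR (interaction log2 0.61, adjusted p = 0.015). It fell with radiation where oleic acid was absent, while with oleic acid present the fall did not pass (adjusted p = 0.077). SCD was lost with median-of-ratios scaling (0.17), TMM (0.12) and edgeR (0.2) and without most single libraries (0.064 to 0.093). Median-of-ratios scaling, TMM and edgeR each gave 1 gene and DESeq2 gave 6, and 4 passed without IR 3, 3 without OA 3 and 1 without most other libraries. CDKN1A (adjusted p = 1), MDM2 (1) and ANGPTL4 (1) did not pass.

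Lists with a difference in the radiation effect were cholesterol synthesis (upward, adjusted p = 6.6e-13; of 26 members, 1 passed upward, 0 downward and 25 did not pass (3 and 0 adjusted over the list alone)) and fatty acid synthesis (upward, adjusted p = 4.1e-09; of 23 members, 1 passed upward, 0 downward and 22 did not pass (5 and 0 adjusted over the list alone)). Others passed without any member beyond the threshold: integrated stress (downward, adjusted p = 0.00014, with adjusted p = 0.23 with an estimated correlation) and NRF2 (downward, adjusted p = 4e-05, with adjusted p = 0.22 with an estimated correlation). Fatty acid oxidation passed downward (adjusted p = 0.0046, and adjusted p = 0.14 with an estimated correlation) and was lost without IR 3 (0.063), OA 3 (0.13) and OA+IR 1 (0.17) and with array weights (0.22). NF-kB passed upward (adjusted p = 0.0043, and adjusted p = 0.13 with an estimated correlation) and was lost without OA 1 (0.12). Mesenchymal genes passed upward (adjusted p = 0.045, and adjusted p = 0.29 with an estimated correlation) and were lost without Ctrl 3 (0.13), IR 2 (0.11), IR 3 (0.11), OA 2 (0.069) and OA+IR 1 (0.3), with a filter of 5 CPM (0.08) and with array weights (0.14). Integrated stress was lost without OA 3 (0.086). The p53 list did not pass (adjusted p = 0.054) but did in 8 leave-one-out fits (0.017 to 0.045), with a pseudocount of 1 (0.049) and without a filter (0.01), and hypoxia (0.065) did without Ctrl 2 (0.021), IR 3 (0.016), OA 3 (0.0043) and OA+IR 1 (0.0019), with TMM (0.042) and with array weights (0.003).

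The other lists did not pass for the interaction: PPAR targets (adjusted p = 0.24), lipid droplets (0.32), mitosis (0.23), G1/S (0.45), DNA repair (0.37), apoptosis (0.68), interferon (0.89), oxidative phosphorylation (0.65), squamous differentiation (0.51), ribosomal proteins (0.32), leukocyte markers (0.89) and fibroblast and endothelial markers (0.053). With array weights G1/S (0.015) and ribosomal proteins (0.0072) passed. Fibroblast and endothelial markers passed with a pseudocount of 1 (0.044), the replicate block (0.034) and in 6 leave-one-out fits (0.0047 to 0.041). Interferon passed upward without IR 1 (5e-04) and downward without IR 2 (0.0069), and ribosomal proteins upward in 5 leave-one-out fits (2.6e-05 to 0.032) and downward without OA+IR 2 (0.024). Oxidative phosphorylation passed downward without OA 1 (0.039) or OA+IR 2 (0.0046), and upward without the 4 libraries at the ends of the within-group axis (3e-05), a setting chosen after seeing the data. Mitosis passed without OA 3 (0.036) and G1/S without OA+IR 1 (0.048).

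On the within-group axis, long non-coding RNA genes lay at a median loading of 1.29 SD (86.2% positive), mitochondrial-encoded genes at 0.941, histones at -0.867 (0% positive), ribosomal proteins at -0.654 and oxidative phosphorylation genes at -0.59. Scores had group means from -0.63 (Ctrl) to 0.511 (OA+IR). They were lowest in Ctrl 3 (-1.78), OA 3 (-1.24) and IR 3 (-1.14) and highest in OA+IR 1 (1.65). Loadings correlated with log2 changes of the 5 comparisons at r = 0.285, 0.331, 0.365, 0.24 and 0.19. The mitochondrial rRNA gene MT-RNR2 stood at 2681 CPM in IR 3, 2438 in OA+IR 1 and 1319 in OA+IR 3, and at 211 to 578 in the others. MT-RNR1 stood at 1355, 1310.4 and 646 CPM in the same 3. Long non-coding RNA held 2.21%, 3.03%, 2.42% and 3.21% of the CPM in Ctrl, IR, OA and OA+IR.

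For histones, 0 of 24 rose, 12 fell and 12 did not pass (0 and 23 adjusted over the list alone) in OA+IR against OA, with a median of -0.36, adjusted p = 8.1e-14 and adjusted p = 0.23 with an estimated correlation. The linker histones H1-4 (log2 -0.46) and H1-2 (-0.51) fell, though reads of histone copies may be shared. The count was 2 with either scaling, 6 without Ctrl 1, 4 without Ctrl 2 or IR 2, 19 without OA 1, 2 without OA 2, OA 3, OA+IR 1 or OA+IR 3 and 23 without OA+IR 2. Against Ctrl, 0 of 24 rose, 19 fell and 5 did not pass (0 and 21 adjusted over the list alone, list test adjusted p = 2.7e-10, and adjusted p = 0.29 with an estimated correlation), with 10 fallen without Ctrl 3 or OA+IR 1 and 11 without OA+IR 3. With the replicate block 11 of 24 histones fell in IR against Ctrl, and 20 with the block on Ctrl, IR and OA libraries alone, a setting chosen after seeing the data. Without a block no histone passed in IR against Ctrl (list adjusted p = 6.1e-09 downward, and adjusted p = 0.34 with an estimated correlation; 3 fell without OA 3), in OA+IR against IR (adjusted p = 0.00024 downward, and adjusted p = 0.51 with an estimated correlation; 3 fell without OA 3 and 7 without OA+IR 2) or in OA against Ctrl (adjusted p = 0.15, and 0.034 without Ctrl 1 and 9e-05 without OA 3). The interaction passed downward (adjusted p = 0.0019, and adjusted p = 0.57 with an estimated correlation) and was lost without Ctrl 1 (0.057), IR 3 (0.3), OA 3 (0.92), OA+IR 1 (0.34) or OA+IR 3 (0.098).

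For mitochondrial-encoded genes, 8 of 13 rose, 0 fell and 5 did not pass (11 and 0 adjusted over the list alone) in OA+IR against Ctrl (adjusted p = 7e-04, and adjusted p = 0.42 with an estimated correlation), including MT-ATP8 (1.64-fold) and MT-ND4 (1.43-fold), with 5 risen with either scaling, 4 without Ctrl 1, Ctrl 2, Ctrl 3, IR 1, IR 2 or OA+IR 1 and 3 without OA+IR 3. Against OA, 2 of 13 rose, 0 fell and 11 did not pass (10 and 0 adjusted over the list alone, list test adjusted p = 3.6e-07, and adjusted p = 0.26 with an estimated correlation). In IR against Ctrl, 1 of 13 rose, 0 fell and 12 did not pass (1 and 0 adjusted over the list alone, list test adjusted p = 0.0051, and adjusted p = 0.51 with an estimated correlation), with 4 risen without OA 3. Against IR, 1 of 13 rose, 0 fell and 12 did not pass (1 and 0 adjusted over the list alone, list test adjusted p = 0.031, and adjusted p = 0.6 with an estimated correlation), lost without IR 3 (0.088), OA+IR 1 (0.058) or OA+IR 3 (0.11) and with a filter of 5 CPM (0.063). In OA against Ctrl, 0 of 13 rose, 0 fell and 13 did not pass (0 and 0 adjusted over the list alone, list test adjusted p = 0.98 downward, with 11 changes positive). The list turned upward and passed without OA 3 (0.0016, 5 risen) and with array weights (0.02, 6 risen). The interaction passed upward (adjusted p = 0.0022, and adjusted p = 0.46 with an estimated correlation) and was lost without Ctrl 3 (0.098) or OA 3 (0.85) and with array weights (0.86). These genes have nuclear copies, so their reads may be shared.

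For ribosomal proteins, 0 of 42 rose, 1 fell and 41 did not pass (0 and 7 adjusted over the list alone) in IR against Ctrl (adjusted p = 1.5e-09 downward, and adjusted p = 0.38 with an estimated correlation), with 40 of 42 changes negative. With the replicate block 11 fell, and 5 fell without OA 3 and 3 without OA+IR 1. Between OA and OA+IR, 0 of 42 rose, 0 fell and 42 did not pass (0 and 0 adjusted over the list alone, list test adjusted p = 1.1e-06 downward, and adjusted p = 0.46 with an estimated correlation), and 5 fell without OA+IR 2. Between Ctrl and OA+IR, 0 of 42 rose, 5 fell and 37 did not pass (0 and 4 adjusted over the list alone, list test adjusted p = 0.0018 downward, and adjusted p = 0.63 with an estimated correlation), including RPS15 (log2 -0.4), and the call was lost without Ctrl 3 (0.092) and OA+IR 1 (0.19). In OA against Ctrl (adjusted p = 0.81; 5 genes rose with the block) and OA+IR against IR (adjusted p = 0.35; 1 gene rose) the list did not pass. In the former it passed upward without Ctrl 3 (0.029) or OA 1 (0.011) and downward without OA 3 (0.04, 1 risen). In the latter it passed upward without IR 3 (0.0058) or OA+IR 1 (0.00055) and with array weights (0.0087).

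For oxidative phosphorylation, 1 of 36 rose, 24 fell and 11 did not pass (1 and 30 adjusted over the list alone) in OA+IR against Ctrl (adjusted p = 9.8e-13 downward, and adjusted p = 0.18 with an estimated correlation), including the complex I genes NDUFS7 (log2 -0.44) and NDUFA4 (-0.54). In IR against Ctrl, 0 of 36 rose, 3 fell and 33 did not pass (0 and 10 adjusted over the list alone, list test adjusted p = 5.5e-10 downward, and adjusted p = 0.22 with an estimated correlation), and 0 fell without Ctrl 1, Ctrl 2 or IR 1, 1 without Ctrl 3 or IR 2, 5 without OA+IR 1 and 9 with the replicate block. Between OA and OA+IR, 0 of 36 rose, 3 fell and 33 did not pass (0 and 15 adjusted over the list alone, list test adjusted p = 5.5e-10 downward, and adjusted p = 0.22 with an estimated correlation), and 6 fell without IR 3, 0 without OA 3, 1 without OA+IR 1 or OA+IR 3 and 11 without OA+IR 2. Between IR and OA+IR, 0 of 36 rose, 4 fell and 32 did not pass (0 and 7 adjusted over the list alone, list test adjusted p = 9.3e-06 downward, and adjusted p = 0.34 with an estimated correlation), and 0 to 2 fell without 1 of 8 libraries. In OA against Ctrl, 0 of 36 rose, 0 fell and 36 did not pass (0 and 0 adjusted over the list alone, list test adjusted p = 7.4e-06 downward, and adjusted p = 0.34 with an estimated correlation), and 3 fell with the block.

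**Figure D4:**
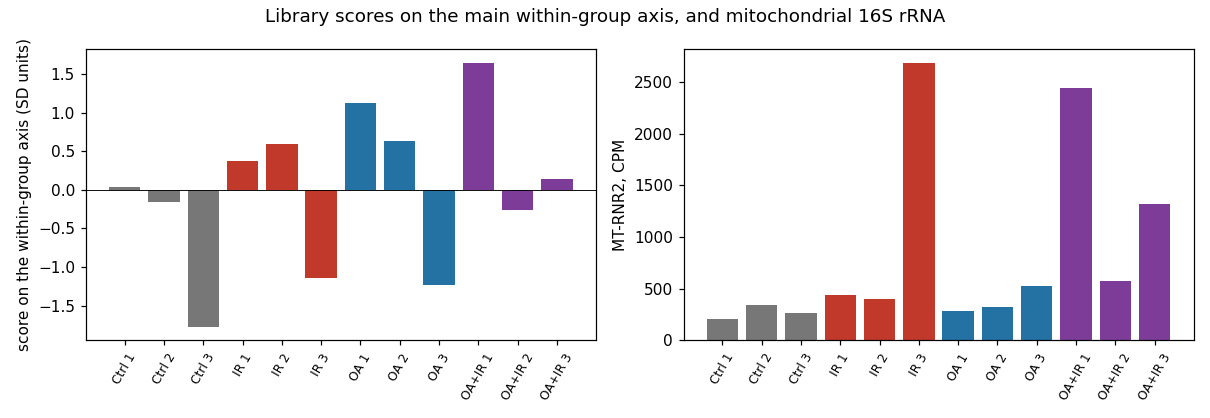
Score of each library on the within-group axis, and its level of MT-RNR2.

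Markers of other cell types were low. The leukocyte gene PTPRC reached at most 0.232 CPM and the T cell gene CD3E 1.58 CPM, while CD14 averaged 41.5 CPM and TYROBP reached 41.7 CPM. The leukocyte list did not pass in IR against Ctrl (adjusted p = 0.66; 1 rose), OA against Ctrl (0.34; 1 fell), OA+IR against Ctrl (0.89; 1 rose and 1 fell), OA+IR against IR (0.42; 1 fell) or OA+IR against OA (0.62; 1 rose), with CD14 the gene that fell and TYROBP the gene that rose. Fibroblast and endothelial markers did not pass in IR against Ctrl (0.84), OA against Ctrl (0.054, and 0.045 without Ctrl 1, 0.048 without IR 3, 0.011 without OA+IR 1 and 0.025 with array weights), OA+IR against Ctrl (0.73; LUM fell and PECAM1 rose), OA+IR against IR (0.76) or OA+IR against OA (0.18, and 0.041 without OA+IR 3).

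In some lists that did not pass, the median, the mean and the test differed in sign. This held for PPAR targets, lipid droplets, integrated stress and fibroblast markers in IR against Ctrl, and for apoptosis, mesenchymal genes, mitochondrial-encoded genes and leukocyte markers in OA against Ctrl. It also held for p53 targets, lipid droplets and the other-cell lists in OA+IR against Ctrl, for the other-cell lists in OA+IR against IR, and for mitosis, G1/S, DNA repair, apoptosis, interferon, hypoxia, ribosomal proteins and leukocyte markers in the interaction.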

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

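The count, the gene and the lists of the next paragraph were marked because the radiation effect differed between cells without and with oleic acid in a test of the interaction. The mitotic and interferon patterns weighed after them were not marked, and were chosen for weighing after their values were seen. Of the tests weighed here, those of the within-group axis against depth and transcript length, of the axis as a covariate and of the estimated correlation were chosen after the result was seen, and the others were written before it.

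The count of genes was 2. SCD had an interaction of log2 0.605. The lists were fatty acid oxidation (adjusted p = 0.0046), fatty acid synthesis (adjusted p = 4.1e-09), cholesterol synthesis (adjusted p = 6.6e-13), integrated and endoplasmic reticulum stress (adjusted p = 0.00014), NRF2 and oxidative stress (adjusted p = 4e-05), NF-kB and secretory inflammation (adjusted p = 0.0043), mesenchymal genes and TGF-beta (adjusted p = 0.045), histones (adjusted p = 0.0019) and mitochondrial-encoded genes (adjusted p = 0.0022). With an estimated correlation only fatty acid synthesis (adjusted p = 0.034) and cholesterol synthesis (adjusted p = 0.0099) passed, and the others, in the same order, had adjusted p = 0.14, 0.23, 0.22, 0.13, 0.29, 0.57 and 0.46. Among other splits of the 12 libraries that kept the design, 2 of 100 gave an interaction count as large as the real 2, the real split included, and the highest other count was 96. The cause of that other count was not tested. An interaction count as small as 2 is no measure of how many genes respond differently. For the comparisons of a pair of groups there were only 10 splits, too few for a share under 0.05: the real split alone (1 of 10) reached 646, 1401, 4529, 2036 and 1149 genes, and the highest other counts were 0, 0, 0, 3 and 0.

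The within-group axis, on which histones and mitochondrial-encoded genes lay at opposite ends, was weighed first. Sequencing depth correlated with the scores at r = -0.156 (permutation p = 0.649, rank correlation -0.336, 95% interval -0.743 to 0.567, and -0.0451 without the 2 farthest depths), so depth was left open. Transcript length correlated with the loadings of protein-coding genes at a rank correlation of 0.313, which met the prediction for a length-dependent technical cause such as RNA integrity or selection, and GC content at 0.0308 did not. The interaction calls for histones (downward) and mitochondrial-encoded genes (upward) turned without OA 3. Over all genes the loadings correlated with the interaction at r = -0.0908. A shift of that sign along the axis would move histones up and mitochondrial-encoded genes down, opposite to these calls. Whether library composition contributed to them was therefore left open.

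The rise of mitotic genes after radiation was weighed second. With the axis score as a covariate the median change in IR against Ctrl was 0.254, so the axis was excluded as its source. That score is partly confounded with treatment. Its loadings come from residuals of the same data, so p-values of that fit are optimistic. Against 10000 lists matched on expression, length and GC content, the median of 0.229 lay at percentile 100 (central range -0.062 to 0.0304), so GC content and length were excluded too. What remains open is whether more cells were in G2 or mitosis at 48 h or the transcripts rose per cell, which bulk values do not separate.

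The fall of interferon genes with oleic acid was weighed last. The median in OA against Ctrl was -0.545 with the axis as a covariate and -0.551 with median-of-ratios scaling, so neither explained it. With the correlation among members estimated from the data, the larger adjusted p of the oleic acid comparisons was 0.088, so a chance shift of a single co-regulated set between cultures could not be excluded.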

How the results depend on the processing

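Of the settings, 24 were planned, and 3 (the axis score as a covariate, 4 libraries at the ends of the axis left out, and a block fitted to Ctrl, IR and OA libraries alone) were chosen after seeing the data. No named gene turned direction. Where no cause is stated, the cause was not tested.

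Counts of genes moved as follows, in the order IR against Ctrl, OA against Ctrl and so on. Without a filter, IR against Ctrl gave 344 and OA+IR against OA 739, and the correlations of oleic acid and radiation effects fell to 0.477 and 0.348, since many genes near 0 were added. A filter of 5 CPM raised those correlations to 0.822 and 0.716, with fewer low genes. Median-of-ratios scaling gave 417 for IR against Ctrl, 753 for OA+IR against OA and 1 for the interaction, TMM gave 1 for the interaction, edgeR 417 and 1, and DESeq2 6 for the interaction. A fit of only the groups compared gave 797 for IR against Ctrl and 490 for OA+IR against OA. Array weights gave 1771, 4169, 1923 (OA+IR against OA) and 11 (interaction), and a radiation correlation of 0.394. The axis covariate gave 2002, 2565, 3816 (OA+IR against IR), 3050 (OA+IR against OA) and 49 (interaction), with optimistic p-values. Leaving out the 4 libraries gave 1625, 2860, 1874 (OA+IR against OA) and 438 (interaction), with correlations of 0.418 and 0.246. Of the gene list tests, 83 passed at the preset correlation and 23 with an estimated correlation.

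The replicate block, fitted to all 12 libraries, gave 1618 for IR against Ctrl and 2687 for OA against Ctrl. For comparisons with OA+IR, where some correlations were under the threshold, it gave 3272 (OA+IR against IR), 2212 (OA+IR against OA) and 6 (interaction). The block on Ctrl, IR and OA libraries alone gave 2981 and 3950. Of 12 libraries, 8 correlated best with a library of their own number, a hint from the data and not from the design. With the block 6 named genes and 2 lists newly passed, among them the mitotic list in OA against Ctrl (0.036), and no call was lost.

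Leaving out 1 library at a time gave 261 to 790 genes for IR against Ctrl, 866 to 1943 for OA against Ctrl, 3024 to 4982 for OA+IR against Ctrl, 1422 to 2248 for OA+IR against IR, 663 to 1210.0 for OA+IR against OA, 1 to 4 for the interaction and 82 to 88 list tests. Correlations ran from 0.575 to 0.666 for oleic acid and from 0.398 to 0.549 for radiation. Some of these fits called more genes than the fit of all libraries and others fewer, and the cause was not tested.

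Lists that turned direction lay on the within-group axis, except interferon genes. Mitochondrial-encoded genes in OA against Ctrl turned with array weights (adjusted p = 0.02), without OA 3 (0.0016) and without the 4 libraries (5e-08). Ribosomal proteins turned in OA against Ctrl without OA 3 (0.04), in OA+IR against Ctrl with the covariate (0.97) and without the 4 libraries (0.92), and in OA+IR against OA without the 4 (0.87). Leave-one-out fits spanned 0.0016 to 1 and 0.011 to 0.82 for these lists in OA against Ctrl. In the interaction, interferon genes turned without IR 2 (0.0069; all fits 5e-04 to 0.99), histones without OA 3 (0.92; 2.5e-12 to 0.92), mitochondrial-encoded genes without OA 3 (0.85; 3.8e-06 to 0.85) and ribosomal proteins without OA+IR 2 (0.024; 2.6e-05 to 0.84). Without the 4 libraries, oxidative phosphorylation (3e-05), histones (0.048) and mitochondrial-encoded genes (0.00098) turned.

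Of 415 results for named genes, 47 lost their call with edgeR, 44 with median-of-ratios scaling, 42 with TMM, 20 with DESeq2, 45 without a filter and 1 with each other pseudocount, and 38 of 404 in fits of only the groups compared. Of 138 list results, 60 lost their call with an estimated correlation, 5 with either scaling and none with the replicate block. In simulated data with the depth of these libraries, 29.9% of 1.5-fold changes were recovered for the interaction and 44.8% for a pair of groups. Depth itself was not varied, and no axis shared between genes was simulated.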

Other observations

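The ERK hypothesis and its members were written before their values were seen, as were the hypotheses on LXR and simple epithelial genes, while the genes that prompted them, and those in the next paragraph, were chosen after their values were seen.

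An EGFR ligand gene and some genes of ERK signalling output were highest in cells given both treatments. The ligand AREG stood at 14.7 ± 1.65 CPM in Ctrl, 21.4 ± 1.91 CPM in IR, 26.9 ± 3.57 CPM in OA and 40.3 ± 1.62 CPM in OA+IR (log2 1.43 in OA+IR against Ctrl, adjusted p = 1.8e-07). The receptor feedback inhibitor ERRFI1 stood at 21.04 ± 2.15 CPM, 31.6 ± 1.93 CPM, 30.95 ± 2.79 CPM and 52.3 ± 3.24 CPM (log2 1.3, adjusted p = 7.2e-08). The transcription factor genes ETV4 (log2 1.5 in OA against Ctrl) and ETV5 (1.71) rose with oleic acid, and ETV5 rose from 9.02 ± 0.136 to 55.5 ± 2.85 CPM with both treatments. The receptor gene EGFR itself stood at 289 ± 17.8 CPM, 291 ± 17.6 CPM, 236 ± 17.4 CPM and 265 ± 24.6 CPM.

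The hypothesis was that ERK output genes not looked at before would move with ETV4, ETV5 and SPRY4 under oleic acid. It held: the median log2 change of 9 such genes in OA against Ctrl was 0.957, with adjusted p = 6.7e-08 in OA against Ctrl and adjusted p = 2e-08 in OA+IR against IR (camera, adjusted over all tests of the 3 hypotheses; 0.0012 and 0.0011 with an estimated correlation). CCND1 (log2 1.36), a cyclin, SPRED2 (1.2), SPRED1 (1.17), DUSP4 (0.996), PHLDA1 (0.96) and SPRY2 (0.69) rose, EPHA4 fell (-1.26), and DUSP6 (0.72) and EPHA2 (0.04) did not pass. The same genes had a median of 0.517 in IR against Ctrl (adjusted p = 1.1e-09). Higher ERK pathway activity is a candidate explanation, and no phosphorylation was measured.

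A second hypothesis was that LXR targets fell with oleic acid, prompted by ABCG1 and SREBF1. Its prediction of a median below 0 was not met in OA against Ctrl, where the unseen members had a median of 0.014 (adjusted p = 0.048 downward, and 0.35 with an estimated correlation). In OA+IR against IR the median was -0.297 (adjusted p = 0.02, and 0.29 with an estimated correlation). Resampled medians took both signs, so the question stayed open, with MYLIP (log2 -1.02) and ABCA1 (-0.95) fallen in OA against Ctrl.

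The last hypothesis was that simple epithelial genes fell, prompted by KRT8 (log2 -1.27, 2432 ± 122 to 1007 ± 84.2 CPM), KRT19 and ELF3 (log2 -1.73). This prediction was not met either: the median of the unseen members was 0.171 (adjusted p = 0.27, and adjusted p = 0.65 in OA+IR against IR). Resampled medians again took both signs, so it stayed open, with KRT18 (log2 -1.05) and MUC1 (-0.65) fallen and ESRP1 (0.72) not passing.

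COL1A1 and COL3A1 reached at most 9.38 and 2.23 CPM outside OA+IR 1.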
